A study of Oryza sativa with 12 samples.

How the data were processed

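Poly(A) RNA of rice seedlings was sequenced in 12 libraries, with 3 libraries in each of 4 groups. The labels name the wild type ZH11, a japonica cultivar, and a line called the grp3/grp162 double mutant, each sampled at 29 °C and at 45 °C. The groups are written WT_29C, WT_45C, dm_29C and dm_45C. Per the labels' protocols, seedlings grew in Kimura B solution at 29 °C and 65% humidity with 13 h of light a day, and heat was applied to 8-day-old seedlings. Libraries carried unique molecular identifiers and a dUTP strand mark and were read as pairs of 150 bp.

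The labels disagree at several points. Heat lasted 18 h in the sample characteristics and 42 h in the treatment protocol, and the length is left open here. Every column name of the deposited table, controls included, also holds the number 42 without a unit. The genotype label of the mutant libraries changes its last number with the replicate, while the titles give the same line for all of them, and the titles were used. The columns of the deposited table that hold the mutant libraries carry another code, and were assigned by elimination after the wild type columns had been matched. The labels do not say that replicates were separate cultures, so every p-value measures the spread between these libraries. The sampling time within the day is not given in the sources used here.

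The deposited values are FPKM (fragments scaled to transcript length and library total), per the file headers, with 1 column per library and 42004 loci. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, without saying which step made which value. The genome build and annotation release are not given in the sources used here, so no coordinates are printed. FPKM summed to between 558435 and 599861 per library, and 13263 loci were at 0 in all of them. Between 22101 and 25116 loci per library lay above 0. Read counts cannot be recovered from these values, so the depth behind each is unknown and no counting intervals are given. None of the 66 pairs of libraries were identical, with a highest correlation of 0.973.

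Everything that follows was computed here from the deposited FPKM. Loci with FPKM of 1 or more in at least 3 libraries were kept, which left 20305. The log2 values were computed here from the deposited FPKM as log2(FPKM + 1), so that a fold change of a locus near 0 FPKM depends on the added 1. All 12 libraries entered a single limma fit with 4 group means and an intensity trend (limma 3.58.1, statmod 1.5.0, R 4.3.3). Adjusted p-values are Benjamini-Hochberg values within a comparison, and an adjusted p under 0.05 counted as passing. The 5 comparisons were heat in the wild type, heat in the double mutant, the genotypes at 29 °C, the genotypes at 45 °C, and the difference between both heat responses. Means are given with standard deviations over 3 libraries, and most fold changes without a standard error. Exact permutation tests of 3 libraries against 3 cannot go below a two-sided p of 0.1, so they are given for the targeted genes alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for the plots.

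The comparisons, tests, named-gene rule, most alternative settings and 11 of the gene lists were set before the data were examined. Another 9 lists (light harvesting, Rubisco, chlorophyll biosynthesis, seed storage, glycine-rich RNA-binding proteins, reactive oxygen scavenging, defence, jasmonate and cell cycle) were written after the table was opened but before the values of their genes were looked at. A list of diterpenoid phytoalexin genes was chosen after its first members had been seen to differ. The lists without the phytoalexin genes hold 214 loci. A further 32 lists given as word patterns were not run, since the deposited table pairs no locus with a product description. Lists with 5 or more tested members were tested with camera at its preset correlation of 0.01, adjusted over 16 lists per comparison, with an estimated correlation and with fry as alternatives. Camera compares a list with all other genes, whereas fry asks whether its own genes move.

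Gene names come from published locus assignments entered by hand. Of the 230 pairs of name and locus, 145 names are a symbol or synonym in the RefSeq gene table, 142 of them on the chromosome of the locus and 3 on another. No locus ID of the deposited table, 0 in all, could be matched to that table directly. The named genes are GRP3 and GRP162 in every comparison. They include the 10 listed genes that rose and the 10 that fell most among those past the threshold with non-overlapping groups and a mean FPKM of 10 or more in the higher group. For each list they include the 3 passing members with the highest mean FPKM, filled up with the highest non-passing members. Loci outside the lists are printed by their ID and were chosen after their values were seen. GRP3 and GRP162 are close relatives, and reads shared between such copies cannot be apportioned here, which also holds for the small heat shock proteins and HSP70 loci.

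The fit was tested on simulated data in which 200 loci had been changed. These were drawn only from loci above a lower bound on mean log2 value, and normal noise was drawn independently for each locus. The rates therefore do not cover loci of low FPKM or a change of as many loci as were called with heat. For heat in the wild type, with 19706 loci tested, it recovered 48% of the changes of 1 log2 unit and 95% of those of 2 log2 units, with 6 wrong calls among 149. For the difference between heat responses, with 19694 loci tested, it recovered 13% and 79%, with 8 wrong calls among 100.

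Replicate numbers recur in all groups, so it was checked whether libraries with the same number deviate together. WT_45C and dm_45C deviations correlated at 0.106, 0.293 and 0.141 for numbers 1, 2 and 3, each above 0.1. Every other pair of groups checked held a value under 0.1, down to -0.122 between WT_29C and WT_45C. Each WT_45C library also correlated best with the dm_45C library of its own number, which held throughout in no other pair of groups checked. The values at 45 °C are low and stand out only among several pairs checked, and the labels give no source for a pairing. A pairing is therefore not established. As a precaution, the fit with a replicate block is given beside the genotype comparison at 45 °C. The alternative settings were another pseudocount (0.1), no filter, a filter at FPKM 5, TPM, median-of-ratios and quantile scaling, each library left out in turn, the replicate block, the compared groups alone, robust empirical Bayes, library weights and a threshold of 1 log2 unit. Leaving out both libraries of mutant replicate 1 (because GRP162 stood high in them), the correlation over all loci tested, removing the 10 most abundant loci, and the block with only the groups compared were added after seeing the data. The 10 loci removed were those of highest mean FPKM over all 12 libraries, and GRP3 is among them. Loci LOC_Os09g30439 (HSP90) and LOC_Os12g19394 (Rubisco small subunit) from the lists were not analysed here.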

Results

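Gene expression was measured in 12 rice libraries, 3 each of WT_29C, WT_45C, dm_29C and dm_45C, to ask how heat changes the seedling transcriptome and whether the response differs in a line labelled as mutated in GRP3 and GRP162. Temperature parted the libraries more than genotype did. Across loci, Pearson correlations of log2(FPKM + 1) ran from 0.835 to 0.858 between WT_29C and WT_45C and from 0.787 to 0.876 between dm_29C and dm_45C. Between genotypes they ran from 0.929 to 0.955 at 29 °C and from 0.920 to 0.960 at 45 °C, against 0.932 to 0.973 within groups. The first principal component held 56.7% of the variance and separated the temperatures, and the second held 9.03%. On the second, every wild type library lay at -2.04 or above. Every library labelled double mutant lay at -4.19 or below, with replicate 1 at -20.73 in dm_29C and -13.67 in dm_45C. The 10 most abundant loci of each library took between 11.4% and 24.2% of its FPKM sum, with the highest shares in WT_29C replicate 2 (21.0%), WT_45C replicate 3 (23.7%) and dm_45C replicate 1.

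GRP3 (LOC_Os03g46770) and GRP162 (LOC_Os12g43600) encode glycine-rich RNA-binding proteins and are the genes the mutant line is named after. GRP3 was among the most abundant transcripts, at a mean FPKM of 4811 ± 835 (SD, n = 3) in WT_29C and 15674 ± 1080 in WT_45C. It rose with heat in the wild type, by a log2 fold change of 1.72 ± 0.525 (limma adjusted p = 0.0273). In the libraries labelled double mutant GRP3 averaged 2260 ± 1806 at 29 °C and 14172 ± 3360 at 45 °C and rose with heat as well (log2 fold change 2.90, adjusted p = 0.00139). Replicate 1 stood apart here too, at 4340 in dm_29C against 1086 and 1355 in the others, within the wild type range of 3879 to 5489, and at 17604 in dm_45C, above the highest WT_45C library (16321). GRP162 averaged 1052 ± 61.6 in WT_29C and 2564 ± 1071 in WT_45C, a difference that did not pass (adjusted p = 0.438) although every WT_45C library lay above every WT_29C library. In 4 of the libraries labelled double mutant GRP162 lay below every wild type library of the same temperature, at 218 and 265 at 29 °C and 746 and 699 at 45 °C. In both replicate 1 libraries it lay above all of them, at 3288 and 12466, which is 2.93 and 3.35 times the highest wild type value. GRP162 therefore went against the genotype label in these libraries, so "the libraries labelled double mutant" is written below. Where "mutant" stands alone it is short for that label, and each genotype direction rests on the label. A frameshift allele need not lower its transcript, so transcript levels alone do not settle the genotype. Adjusted over these 2 genes alone, GRP3 passed as lower in dm_29C.

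Between genotypes neither gene passed. The log2 difference of GRP3 was -1.36 at 29 °C (adjusted p = 0.439, exact permutation p = 0.2) and -0.17 at 45 °C (adjusted p = 0.959, exact p = 0.6). For GRP162 it was -0.87 (adjusted p = 0.859, exact p = 0.4) and -0.37 (adjusted p = 0.956, exact p = 0.9), whereas its mean FPKM was higher in the libraries labelled double mutant, 1257 ± 1759 at 29 °C and 4637 ± 6780 at 45 °C, through replicate 1. The heat rise of GRP3 in the wild type no longer passed without the filter (adjusted p = 0.33), with quantile scaling (0.0504), without WT_29C replicate 1 (0.052) or 2 (0.0899), or without WT_45C replicate 1 (0.0788), 2 (0.0559) or 3 (0.0667), against 0.00766 to 0.33 over all 19 alternatives. Its rise in the libraries labelled double mutant ended without the filter (0.0879, against 0.000435 to 0.0879 over 19 alternatives). GRP162 passed with heat in the libraries labelled double mutant without dm_29C replicate 1 (0.0429) and without both replicate 1 libraries (0.0139), against 0.0139 to 0.817 over 20 alternatives, and in the wild type without both of these (0.0134, against 0.0134 to 0.65). Both replicate 1 libraries were left out because GRP162 stood high in them, so these values are no independent test of the libraries labelled double mutant. For heat in the wild type these libraries enter only through the spread shared by all groups, with a standard error of 1.09 for GRP162. Their removal, chosen on GRP162 itself, also changes that spread. The exact permutation p of heat in the wild type was 0.1 for both genes, the lowest possible. The replicate block, the fit with only the groups compared, robust empirical Bayes and library weights were not run for these genes.

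**Figure D1:**
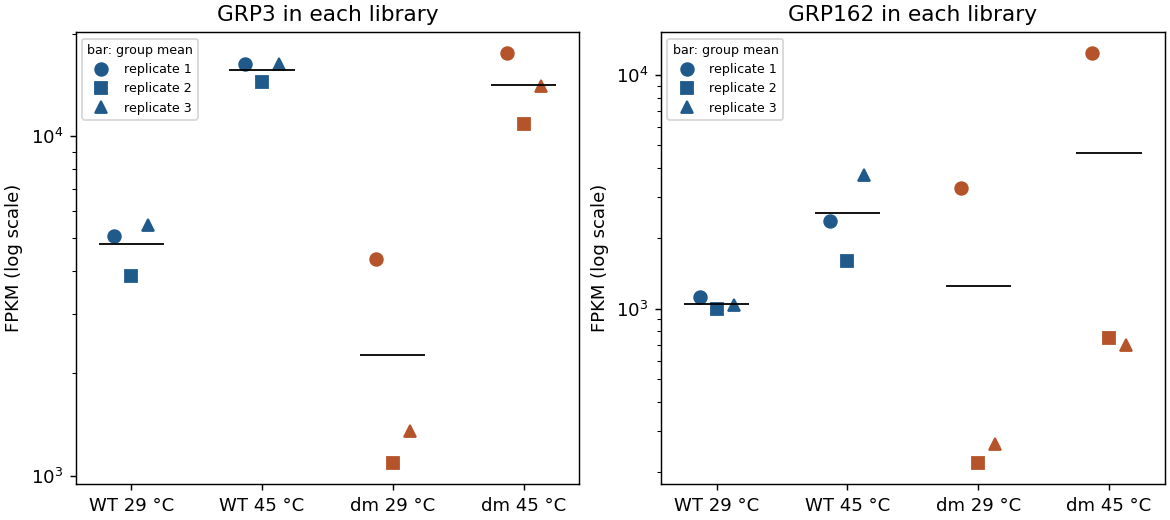
FPKM of GRP3 and GRP162 on a log axis in each of the 12 libraries, with a bar at each group mean. The replicate 1 libraries labelled double mutant stand at 3288 and 12466 for GRP162, above every wild type library of their temperature.

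Heat in the wild type raised the small heat shock proteins, which hold unfolding proteins in solution, more than any other list. All 9 tested members rose, with a median log2 fold change of 5.03 (camera adjusted p = 3.28e-11, and adjusted p = 0.187 with an estimated correlation). HSP17.9A went from 14.4 ± 3.03 to 529 ± 275 FPKM and HSP18.0 from 13.1 ± 2.16 to 467.7 ± 111. HSP16.9A rose from 1.83 ± 0.113 to 433 ± 305, HSP26.7 by 6.97 log2 units, and HSP16.9B, HSP23.2 and HSP17.4 by 5.58, 5.28 and 4.82. Of the HSP70 chaperones 5 of 7 rose (camera adjusted p = 6.32e-05, and adjusted p = 0.234 with an estimated correlation), among them HSP71.1 from 453.6 ± 107 to 1492 ± 181 and the plastid form HSP70CP1 from 96.3 ± 19.4 to 191 ± 3.64. Of the HSP90 chaperones 4 of 6 rose (camera adjusted p = 0.00287, and adjusted p = 0.394 with an estimated correlation), and LOC_Os04g01740 went from 0.22 ± 0.197 to 198 ± 66.2. Of the thermotolerance factors 9 of 12 rose, including the co-activator MBF1c from 5.3 ± 1.69 to 113 ± 12.8 and the immunophilin FKBP62 from 46.3 ± 7.46 to 86.6 ± 15.3 (camera adjusted p = 1.19e-06, and adjusted p = 0.234 with an estimated correlation). Every heat library lay above every control library for each of these genes, and none of their calls was lost in the 23 alternatives run for single genes, which include neither library weights nor a log2 bound. Heat stress transcription factors, the activators and repressors of such genes, went both ways, with 6 of 20 rising and 4 falling and no shift of the list (camera adjusted p = 0.235). HsfB2c rose 4.77-fold and HsfA2c 2.6-fold, whereas HsfA1 fell from 37 ± 5.7 to 18.3 ± 4.05 and HsfA2d fell by 1.10 log2 units, a call that ended without WT_45C replicate 3 (adjusted p = 0.0519, against 0.00336 to 0.0519 over 23 alternatives).

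Genes of abscisic acid signalling and dehydration also rose in the wild type, 8 of 15 (camera adjusted p = 4.99e-05, and adjusted p = 0.382 with an estimated correlation). LEA3, a late embryogenesis abundant protein that accumulates on drying, went from 0.103 ± 0.0611 to 126 ± 80.9 FPKM, and the transcription factor bZIP23 from 11.8 ± 1.89 to 34.2 ± 13.3. Chlorophyll breakdown and senescence genes rose at 5 of 9 loci (camera adjusted p = 0.00221, and adjusted p = 0.404 with an estimated correlation). RCCR1, a reductase of chlorophyll catabolites, rose 2.54-fold, and its call ended without WT_29C replicate 2 (adjusted p = 0.0572) or WT_45C replicate 2 (0.0565; over 23 alternatives 0.00475 to 0.0572). Circadian clock genes rose at 6 of 13 loci (camera adjusted p = 0.0428, and adjusted p = 0.404 with an estimated correlation), with the evening gene LUX from 14.5 ± 6.88 to 64.1 ± 25.6 and PRR59 from 8.2 ± 0.674 to 19.7 ± 3.58. The clock call was also lost with the filter at FPKM 5 (0.0657), median-of-ratios (0.0694) and quantile scaling (0.075), without the 10 most abundant loci (0.0611), without WT_29C replicate 2 (0.061) or 3 (0.0544), without WT_45C replicate 2 (0.0732), and without both mutant replicate 1 libraries (0.0537), against 1.68e-06 to 0.404 over all 24 alternatives. Scavengers of reactive oxygen rose at 5 of 13 loci, without a shift of the list that passed (camera adjusted p = 0.0531). The cytosolic superoxide dismutase SODCC2 went from 302 ± 35.3 to 1570 ± 229, and the ascorbate peroxidase APX1 rose 2.31-fold. Endoplasmic reticulum chaperones rose at 3 of 11 loci (camera adjusted p = 0.107), with the disulfide isomerase PDIL1-1 up 2.02-fold and the calnexin CNX 2.79-fold.

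Single cell cycle and Rubisco genes fell in the wild type, without a list shift that passed in camera. The replication helicase subunit MCM2 fell from 13.1 ± 1.72 to 2.24 ± 1.23 FPKM, 1 of 2 falls among 5 tested cell cycle genes (camera adjusted p = 0.107). Of the Rubisco list 4 loci were tested, too few for a list test, and 2 of its 3 small subunit genes fell while the activase RCA did not pass (log2 fold change -0.04, adjusted p = 0.961), with RBCS2 falling by 1.38 log2 units. That call ended without the filter (adjusted p = 0.0783), without WT_29C replicate 1 (0.0698) and without WT_45C replicate 1 (0.0796) or 3 (0.0549), against 0.0113 to 0.0796 over 23 alternatives. Light-harvesting and photosystem genes rose at 5 of 16 loci and fell at 3 (camera adjusted p = 0.474, median -0.0183, mean 0.191, upward). The 3 that fell were PetE (1523 ± 567 to 696 ± 74.4 FPKM), PsbP (1334 ± 546 to 621 ± 57) and PsbS1 (94 ± 39.1 to 27.7 ± 17.2). Their calls were lost in 7, 6 and 5 of 23 alternatives (adjusted p up to 0.123, 0.0898 and 0.134). Among members at low FPKM, picked after their values were seen, LHCB2 averaged 1.74 ± 0.972 and 11.3 ± 3.88, and CAB2R 14.3 ± 8.46 and 4.2 ± 0.348. Chlorophyll biosynthesis genes rose at 1 of 8 and fell at 3 (camera adjusted p = 0.842). YGL1, a chlorophyll synthase, fell by 1.15 log2 units from 62 ± 18.9, while the reductase DVR rose from 15.7 ± 4.01 to 41.1 ± 2.64. Jasmonate genes fell at 3 of 12 loci (camera adjusted p = 0.0593), with the cyclase AOC at a log2 fold change of -1.21 from 42.9 ± 17.6. None of 8 defence genes passed, 0 by limma at an adjusted p under 0.05 (camera adjusted p = 0.235). Glycine-rich RNA-binding genes included 1 riser of 6, GRP3 (camera adjusted p = 0.225). Of 15 root markers 3 were measurable, and the silicon channel Lsi1 fell from 30.6 ± 7.3 to 1.78 ± 0.393, while most others lay at or near 0 in all groups although the labels say whole plant. Of 7 seed storage markers GLUA2 alone was measurable (6.47 ± 1.19 and 3.31 ± 1.47, adjusted p = 0.0236), and its fall no longer passed without WT_29C replicate 2 (0.0503) or 3 (0.0773), without WT_45C replicate 2 (0.0968) or 3 (0.0684), or with only the groups compared (0.0726), against 0.00793 to 0.0968 over 23 alternatives.

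Counted over all 20305 loci tested, 2701 rose and 3204 fell with heat in the wild type, 29.1% of those tested. Groups did not overlap at 42.6% of all tested loci, against 10% by chance. Counts adjusted over the list alone matched these for small heat shock proteins (9), HSP70 (5), HSP90 (4), thermotolerance (9), abscisic acid (8) and clock genes (6), and gave 6 instead of 5 for chlorophyll breakdown. For heat stress factors they were 8 up and 5 down, for light-harvesting genes 5 and 4, and for Rubisco genes 0 and 3. The largest changes outside the lists, picked after their values were seen, were LOC_Os01g68290 (0.66 ± 0.628 to 1362 ± 207 FPKM) and LOC_Os04g28420 upward and LOC_Os10g36500 (138 ± 58.4 to 0.237 ± 0.111) and LOC_Os12g33150 downward. Without WT_45C replicate 1, 1781 loci rose. With fry, which asks whether a list's own genes move, 10 of 16 lists passed, among them oxygen scavengers (adjusted p = 0.00965), glycine-rich genes (0.00965) and cell cycle genes (0.0146), and 14 passed when both directions were allowed. In camera, jasmonate genes passed without WT_29C replicate 1 (0.0174) or 3 (0.0023), WT_45C replicate 3 (0.0137) or dm_45C replicate 1 (0.0467) and with no filter (0.0253), against 0.000198 to 0.932 over 24 alternatives. Oxygen scavengers passed without WT_29C replicate 1 (0.028), WT_45C replicate 1 (0.0317) or dm_45C replicate 1 (0.0467), with TPM (0.0452), median-of-ratios (0.0322) and quantile scaling (0.016) and without the 10 most abundant loci (0.0386), against 3.52e-06 to 0.439 over 24 alternatives.

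In the libraries labelled double mutant, heat again raised all 9 small heat shock proteins, with a median log2 fold change of 4.69 (camera adjusted p = 2.22e-09, and adjusted p = 0.288 with an estimated correlation). HSP26.7 went from 0.917 ± 0.274 to 462 ± 384 FPKM, HSP18.0 from 22.1 ± 4.93 to 622 ± 240 and HSP17.4 from 14.2 ± 4.41 to 473 ± 217. HSP70 genes rose at 5 of 7 loci (camera adjusted p = 0.00126, and adjusted p = 0.315 with an estimated correlation) and HSP90 genes at 4 of 6 (camera adjusted p = 0.00456, and adjusted p = 0.315 with an estimated correlation). HSP71.1 went from 537.5 ± 244 to 1637 ± 229 and LOC_Os04g01740 from 0.557 ± 0.0603 to 203 ± 110. Thermotolerance factors rose at 9 of 12 loci, with MBF1c from 11.1 ± 5.22 to 100.2 ± 33.4 (camera adjusted p = 1.04e-05, and adjusted p = 0.315 with an estimated correlation). Heat stress factors rose at 7 of 20 loci and fell at 3, with a median of -0.0117 and a mean of 0.246 (camera adjusted p = 0.455, upward). HsfC1b rose 5.82-fold, and HsfA2d fell from 21 ± 1.65 to 6.31 ± 3.16.

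Clock genes rose at 7 of 13 loci and fell at 1 in these libraries (camera adjusted p = 0.00321, and adjusted p = 0.315 with an estimated correlation). LUX went from 10.8 ± 0.729 to 134.5 ± 47.7 and PRR1/TOC1 from 7.54 ± 1.45 to 38.5 ± 13.7, while the morning gene LHY/CCA1 fell from 152 ± 41.9 to 32.3 ± 29.8. Dehydration genes rose at 8 of 15 loci (camera adjusted p = 0.000299, and adjusted p = 0.315 with an estimated correlation), with LEA3 from 0.4 ± 0.197 to 70.3 ± 57.8 and the proline synthesis enzyme P5CS1 up 2.27-fold. Chlorophyll breakdown genes rose at 6 of 9 loci (camera adjusted p = 0.00456, and adjusted p = 0.373 with an estimated correlation), with NYC1, a chlorophyll b reductase, from 51.5 ± 6.85 to 142.5 ± 36.7. Oxygen scavengers rose at 6 of 13 loci and fell at 1 (camera adjusted p = 0.0627), with SODCC2 up 4.23-fold and SODCC1 falling by 1.15 log2 units. MCM2 fell by 2.37 log2 units to 2.58 ± 1.09 among 2 falling cell cycle genes of 5 (camera adjusted p = 0.0693), and RBCS1 from 2344 ± 253 to 654.6 ± 435 among 3 falling small subunit genes of 3, while RCA did not pass (log2 fold change -0.46, adjusted p = 0.496). The call of RBCS1 ended without both replicate 1 libraries (adjusted p = 0.105, against 0.00251 to 0.105 over 23 alternatives), as did that of RBCS3 (0.118, against 0.00477 to 0.118). RBCS2 passed (adjusted p = 0.0488) and lost its call in 15 of 23 alternatives (0.0203 to 0.288), namely without WT_29C replicate 2 (0.0624), WT_45C replicate 1 (0.0653), 2 (0.0527) or 3 (0.0603), dm_29C replicate 1 (0.154), 2 (0.0787) or 3 (0.0767), dm_45C replicate 1 (0.131) or 3 (0.148), and in 6 other settings. Light-harvesting genes rose at 5 of 16 loci and fell at 2 (camera adjusted p = 0.126), with LHCA2 up 5.12-fold. The 2 that fell were PetE (1362 ± 264 to 696 ± 326 FPKM) and PsbS1 (124 ± 37.1 to 33.7 ± 28.1). Their calls were lost in 9 and 4 of 23 alternatives (adjusted p up to 0.263 and 0.136). Of 3 measurable root markers Lsi1 fell from 44.7 ± 8.15 to 4.84 ± 2.36 and HMA3 rose from 0.323 ± 0.125 to 1.24 ± 0.0503 (adjusted p = 0.0402). The call of HMA3 ended without dm_29C replicate 1 (0.0689), 2 (0.119) or 3 (0.0742), without dm_45C replicate 1 (0.089), 2 (0.0754) or 3 (0.0886), without both replicate 1 libraries (0.131), with a pseudocount of 0.1 (0.116) and with quantile scaling (0.0717), against 0.026 to 0.131 over 22 alternatives.

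The remaining lists did not pass in camera in these libraries. Endoplasmic reticulum chaperones rose at 2 of 11 loci (camera adjusted p = 0.881, median -0.0641, mean 0.0287), chlorophyll biosynthesis genes at 1 of 8 (0.359) and glycine-rich genes at 1 of 6 (0.114). Jasmonate genes rose at 1 of 12 loci and fell at 3, and their median of -0.294 and mean of 0.155 differ in sign (camera adjusted p = 0.527, downward). Of 8 defence genes 1 rose, WRKY76 (camera adjusted p = 0.114), and its call ended without dm_29C replicate 1 (adjusted p = 0.0519) or dm_45C replicate 3 (0.0736) and without both replicate 1 libraries (0.0743), against 0.00349 to 0.0743 over 23 alternatives. Over all loci 3102 rose and 3328 fell, 31.7% of those tested, and groups did not overlap at 47.6%, against 10% by chance. With both replicate 1 libraries left out, 2130 rose and 1692 fell. LOC_Os01g68290 again rose most (3.98 ± 1.72 to 1333 ± 127 FPKM) and LOC_Os12g33150 fell most (1697 ± 722 to 26.3 ± 25.9), both picked after their values were seen. Adjusted over the list alone, 11 thermotolerance, 9 dehydration, 8 clock, 7 chlorophyll breakdown and 5 HSP90 genes rose. With fry 10 of 16 lists passed, among them glycine-rich genes (adjusted p = 0.000691), cell cycle genes (0.00893) and oxygen scavengers (0.00899), and 15 passed when both directions were allowed. In camera, cell cycle genes passed without dm_29C replicate 1 (0.022) or both replicate 1 libraries (0.0213), and oxygen scavengers without WT_45C replicate 3 (0.0475), dm_45C replicate 1 (0.0222) or both replicate 1 libraries (0.0416), with no filter (0.0332), median-of-ratios (0.0432) or quantile scaling (0.03) and without the 10 most abundant loci (0.047), against ranges of 0.00527 to 0.39 and 5.84e-07 to 0.437 over their alternatives.

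**Figure D2:**
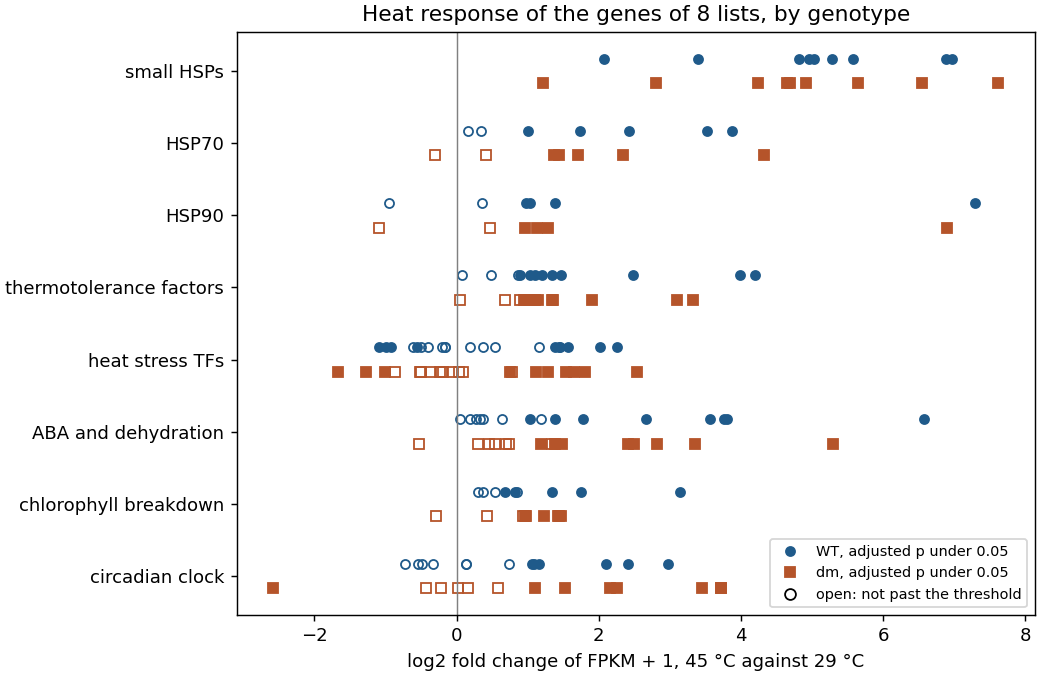
Log2 fold change with heat of each tested member of 8 gene lists, by genotype label, with filled points for an adjusted p under 0.05. All 9 small heat shock proteins are filled and lie above 0 in both genotypes.

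The heat responses of both genotypes largely coincided. All 9 small heat shock proteins rose and MCM2 fell in both, and 1972 loci rose in both where independent lists would share 412.6. Falls were shared at 2312 loci, where independent lists would share 525.1, and loci that rose in one genotype and fell in the other numbered 2 and 4. Over 3728 loci chosen on the mean of both responses, the median ratio of the response in the libraries labelled double mutant to that in the wild type was 1.036 (jackknife standard error 0.113). The Pearson correlation across these loci was 0.939 (standard error 0.0142), where loci are not independent replicates and the choice of loci on the mean of both responses raises the value by leaving out loci whose responses oppose. Over all 20305 loci tested, a value added after seeing the data, it was 0.859. The ratio was 0.902 over loci called in the wild type and 1.18 over loci called in the libraries labelled double mutant, so its side of 1 follows the choice of loci.

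**Figure D3:**
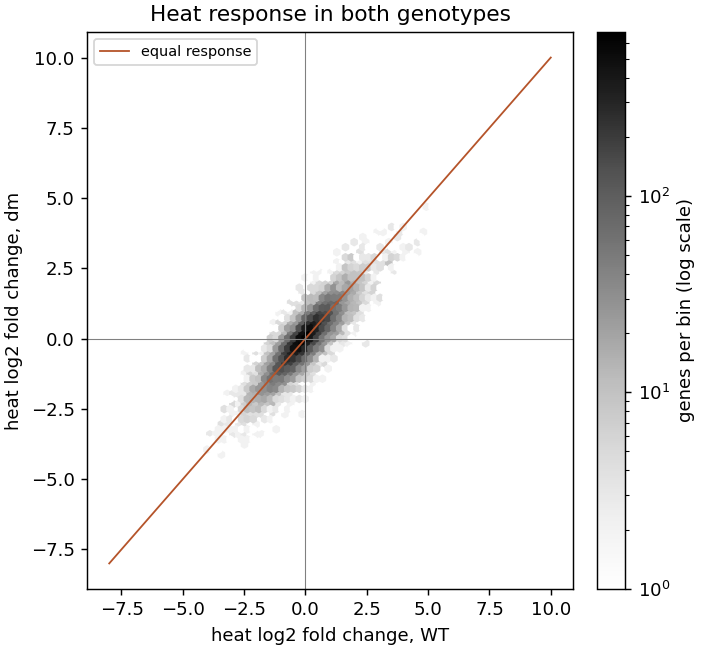
Heat log2 fold change in the libraries labelled double mutant (vertical) against that in the wild type (horizontal) for all tested loci, shaded by number of loci, with a line of equal response. Loci lie along the line, and the correlation is 0.859 over all loci and 0.939 over the 3728 chosen on the mean of both responses.

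Without heat, the genotype comparison asks what differs in growing seedlings labelled double mutant. LOC_Os03g43100 stood at 26.6 ± 4.17 FPKM in dm_29C against 0.133 ± 0.126 in WT_29C (adjusted p = 1.21e-06), with every library labelled double mutant, replicate 1 included, at 22.1 or more and every wild type library at 0.27 or less. LOC_Os03g02470 stood at 104 ± 86.5 against 0.0433 ± 0.0451 (adjusted p = 0.025). LOC_Os05g11320 was lower, at 27.9 ± 11.9 against 635.7 ± 669 (adjusted p = 0.0405), where WT_29C replicate 3 stood at 1408 and the others at 246 and 254, as was LOC_Os06g28050, at 4.63 ± 2.4 against 21.4 ± 5.56 (adjusted p = 0.041). These loci belong to no list and were chosen after their values were seen. No heat shock protein, clock or dehydration gene differed past the threshold, though 1 dehydration gene was higher when adjusted over the list alone. Chlorophyll breakdown genes (median log2 difference -0.387), chlorophyll biosynthesis genes (-0.264) and jasmonate genes (-0.278) were shifted downward as lists (camera adjusted p = 0.0345 each), with 0 members past the threshold in limma, 0 adjusted over the list alone, and adjusted p = 0.869 with an estimated correlation for each. RCCR1 differed by -0.93 (adjusted p = 0.438), YGL1 by -0.46 (0.564) and TIFY10A by -0.51 (0.804). The other 13 of the 16 lists did not pass, and no fry test of a list passed (lowest adjusted p 0.811). Without WT_29C replicate 3, light-harvesting genes passed as well (0.0105, against 0.0105 to 0.922 over 24 alternatives).

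In all, 40 loci were higher and 9 lower in dm_29C, 49 of 20305, and 1985 had an unadjusted p under 0.05. Groups did not overlap at 14.1% of all tested loci, against 10% by chance. Single libraries moved the number of higher loci to 21, 17 and 14 without WT_29C replicate 1, 2 and 3, to 21 without WT_45C replicate 1, and to 15, 8 and 20 without dm_29C replicate 1, 2 and 3. The number of lower loci became 2 and 0 without WT_29C replicate 1 and 3, 5 without WT_45C replicate 1, and 3, 1 and 2 without dm_29C replicate 1, 2 and 3. The call of LOC_Os03g43100 held in all 23 alternatives (highest adjusted p 0.00129), whereas those of LOC_Os03g02470, LOC_Os06g28050 and LOC_Os05g11320 were lost in 9, 17 and 15 of 23, with adjusted p up to 0.229, 0.179 and 0.207. Without each single WT_29C library, without WT_45C replicate 1, and without dm_29C replicate 1 or 2, all 3 of these calls were lost, and LOC_Os06g28050 and LOC_Os05g11320 also lost theirs without dm_29C replicate 3 (0.0595 and 0.144) and LOC_Os06g28050 without WT_45C replicate 2 (0.0577). The jasmonate shift turned upward without WT_29C replicate 2 (adjusted p = 0.599). It also fell short without dm_29C replicate 1 (0.0608) or 2 (0.163). Chlorophyll biosynthesis fell short without WT_29C replicate 1 (0.512) and dm_29C replicate 1 (0.0604) or 2 (0.177), and chlorophyll breakdown without WT_29C replicate 1 (0.0531) or 3 (0.0739) and dm_29C replicate 1 (0.0604) or 2 (0.163). All 3 shifts (breakdown, biosynthesis, jasmonate) also fell short with a pseudocount of 0.1 (0.051, 0.051 and 0.0838), the filter at FPKM 5 (0.0862, 0.0862 and 0.295), median-of-ratios (0.0502, 0.0502 and 0.0828) and quantile scaling (0.0706, 0.0898 and 0.115), without the 10 most abundant loci (0.0503, 0.0539 and 0.0539) and without both mutant replicate 1 libraries (0.0578 each). Chlorophyll biosynthesis fell short with no filter (0.0506) and with the replicate block (0.0569), and jasmonate with TPM (0.0505). Over 24 alternatives the adjusted p ran from 2.19e-05 to 0.869 for jasmonate, 0.0105 to 0.869 for chlorophyll biosynthesis and 0.0233 to 0.869 for chlorophyll breakdown genes.

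After heat, the same comparison found LOC_Os03g43100 again, at 35.4 ± 8.99 FPKM in dm_45C against 0.107 ± 0.144 in WT_45C (adjusted p = 4.2e-07). LOC_Os02g06630 (2.9 ± 0.71 against 0.113 ± 0.0971) and LOC_Os03g60550 (13.8 ± 1.86 against 3.89 ± 0.309) were higher as well, and LOC_Os04g09860 was lower (1.64 ± 0.958 against 18.8 ± 8.88). These were the 4 loci past the threshold, 3 higher and 1 lower, named after their values were seen, and the groups did not overlap at any of them. No list member passed, and the small heat shock proteins had a median of 0.0524 and a downward camera test (adjusted p = 0.989). Clock genes were shifted upward (camera adjusted p = 0.0235), with 5 higher and 1 lower adjusted over the list alone, LUX at a log2 difference of 1.08 and LHY/CCA1 at -1.62. With no sampling time given, another time of day cannot be told apart from an effect of genotype for the clock genes. Chlorophyll breakdown genes (camera adjusted p = 0.00888) and endoplasmic reticulum chaperones (0.0229) were shifted downward, with 0 and 2 lower adjusted over the list alone, and RCCR1 at -1.05 and the calreticulin CRT at -0.71. The adjusted p was 0.775 with an estimated correlation for each of these 3 lists.

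At 45 °C 1618 loci had an unadjusted p under 0.05, and groups did not overlap at 13.3% of all tested loci, against 10% by chance. With the replicate block, 1 locus was higher and 0 lower in the fit of all libraries, and 5 were higher and 0 lower with only the groups compared; LOC_Os03g43100 kept its call in all 23 alternatives (highest adjusted p 0.00124), while the block ended the other 3 calls (adjusted p = 0.0863 each). The number of higher loci became 1 without WT_29C replicate 1 or WT_45C replicate 1, 5, 5 and 6 without dm_29C replicate 1, 2 and 3, and 5, 7 and 30 without dm_45C replicate 1, 2 and 3. The number of lower loci became 0 without any single WT_29C library or WT_45C replicate 1 or 3, and 3 and 14 without dm_45C replicate 2 and 3. LOC_Os02g06630 and LOC_Os03g60550 lost their calls without WT_29C replicate 1, any single WT_45C library or dm_45C replicate 1 (adjusted p up to 0.104 and 0.129). LOC_Os04g09860 lost its call without any single WT_29C library, WT_45C replicate 1 or 3, or dm_45C replicate 1 or 2 (up to 0.13). The clock shift fell short without WT_45C replicate 3 (0.157) and dm_45C replicate 1 (0.0817) or 3 (0.0856), the chlorophyll breakdown shift without dm_45C replicate 1 (0.0817) or 2 (0.0613), and the reticulum shift without WT_45C replicate 3 (0.275) and dm_45C replicate 1 or 2 (0.0817 and 0.0613). Without both mutant replicate 1 libraries, in which GRP162 goes against the label, none of these 3 shifts passed (0.101 each), and the reticulum shift also ended with quantile scaling (0.0771). Defence genes passed without WT_45C replicate 3 (0.00236, against 0.00236 to 0.997 over 24 alternatives). Over 24 alternatives the adjusted p ran from 0.00335 to 0.775, 8.19e-05 to 0.91 and 0.000997 to 0.91 for these lists.

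Whether the heat response itself differed was tested as the interaction. LOC_Os02g36830, LOC_Os10g20890 and LOC_Os04g03050 responded more negatively in the libraries labelled double mutant, by log2 differences of -2.16, -2.74 and -3.20 (adjusted p = 0.0446 each). All 3 averaged 1.09 FPKM or less in the wild type at both temperatures and in dm_45C, and stood at 3.56 ± 0.22, 8.39 ± 3.14 and 12 ± 2.95 FPKM in dm_29C. They were named after their values were seen. No locus responded more positively, 0 by limma, while 1039 loci had an unadjusted p under 0.05. Small heat shock proteins did not pass as a list (median -0.34, camera adjusted p = 0.231), nor did MBF1c (-1.09, adjusted p = 0.932) or GRP3 (1.19, adjusted p = 0.974). Clock genes (median log2 difference 0.366, camera adjusted p = 0.0139), chlorophyll biosynthesis genes (0.352, 0.0479) and jasmonate genes (0.602, 0.0449) responded more positively as lists, and endoplasmic reticulum chaperones more negatively (-0.14, 0.0449). None of these 4 passed with an estimated correlation (adjusted p = 0.857 each), and 0 of their members passed alone in limma or adjusted over the list alone. For chlorophyll breakdown genes the median (0.12) and mean (-0.136) differ in sign (camera adjusted p = 0.78).

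The 3 interaction calls were lost in most fits without 1 library. Their number fell to 0 without any single WT_29C or WT_45C library and without dm_29C replicate 1 or 2 or dm_45C replicate 1, to 1 without dm_29C replicate 3 or dm_45C replicate 3 (in the latter not one of the 3), and rose to 9 without dm_45C replicate 2; 2 loci responded more positively without dm_45C replicate 2 or 3. The clock shift passed in every fit without 1 library, whereas the jasmonate shift ended without WT_29C replicate 2 (adjusted p = 0.938), WT_45C replicate 1 (0.283) or 2 (0.0969), dm_29C replicate 2 (0.116), or dm_45C replicate 2 (0.129) or 3 (0.146). Chlorophyll biosynthesis ended without WT_29C replicate 1 (0.566), WT_45C replicate 1 (0.245) or 2 (0.0632), dm_29C replicate 2 (0.155) or 3 (0.0519), or dm_45C replicate 2 (0.349) or 3 (0.067). The reticulum shift ended without WT_29C replicate 2 (0.169), WT_45C replicate 3 (0.194), dm_29C replicate 2 (0.116), or dm_45C replicate 1 (0.0671) or 2 (0.129). These 3 shifts (jasmonate, biosynthesis, reticulum) also ended with a pseudocount of 0.1 (0.0952, 0.0613 and 0.0613), no filter (0.051, 0.0662 and 0.139), the filter at FPKM 5 (0.188, 0.0713 and 0.052), median-of-ratios (0.0511 each) and quantile scaling (0.0565 each). Chlorophyll biosynthesis ended with the replicate block (0.0801) and the reticulum shift without both mutant replicate 1 libraries (0.0763), whereas the clock shift passed in all of these. Other lists passed in single fits: small heat shock proteins without WT_45C replicate 3 (0.00223) or dm_29C replicate 1 (0.044), HSP70 genes without dm_29C replicate 1 (0.044), dehydration and defence genes without WT_45C replicate 3 (0.0272 and 0.0015), and light-harvesting genes without WT_29C replicate 3 (0.00694), dm_29C replicate 1 (0.0489), dm_45C replicate 1 (0.0485) or both mutant replicate 1 libraries (0.0249). Each of these lists ran up to an adjusted p of 0.957 or more over 24 alternatives. Over 24 alternatives the adjusted p of the jasmonate, biosynthesis and reticulum lists ran from 6.47e-05 to 0.957, 0.00401 to 0.957 and 0.00298 to 0.957. That of the clock list ran from 0.00111 to 0.957, and its call was lost with an estimated correlation and with fry. For the clock list, groups sampled at unlike times of day cannot be told apart from an effect of genotype.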

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

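The splits of the samples were planned, whereas the tests of GRP162 in the replicate 1 libraries and of the clock genes were chosen only after the results were seen.

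LOC_Os02g36830 (-2.16), LOC_Os10g20890 (-2.74) and LOC_Os04g03050 (-3.20) were picked out because their log2 heat responses differed between genotypes in the interaction test. As lists, clock genes (camera adjusted p = 0.0139), endoplasmic reticulum chaperones (0.0449), jasmonate genes (0.0449) and chlorophyll biosynthesis genes (0.0479) differed in the same test, but none of these 4 passed with an estimated correlation (adjusted p = 0.857 each) or with fry (0.957 each). Splitting the samples otherwise gave 3 or more loci in 8 of 100 splits, the real split included. Each of these splits keeps the real genotype labels at 29 °C and so carries the genotype differences found there. The count therefore cannot tell how many loci chance alone would give, and chance is not excluded. The highest other split gave 69 loci; it exchanges the genotype labels at 45 °C alone and so measures the sum of the genotype differences at both temperatures.

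For the pairwise comparisons 10 splits exist, too few for a share under 0.05. Each other split mixes both groups, so a real difference widens the spread within its groups and lowers its calls. Where the difference is large, as with heat, few calls in the other splits are thus fixed in advance and do not measure chance. The real split gave the most calls in each, 1 of 10 splits: 5905 against at most 1 for heat in the wild type, 6430 against at most 58 for heat in the libraries labelled double mutant, 49 against at most 2 between genotypes at 29 °C, and 4 against at most 3 at 45 °C. Taking replicate numbers as pairs at 45 °C, which is not established, 4 splits part all 3 pairs, the real split among them. The others of these called 1 to 3 loci, and the 6 splits that part 1 pair called 0 to 2.

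GRP162 stood above every wild type library of its temperature in both replicate 1 libraries labelled double mutant. For a wild type library under a mutant label, loci were sought that the other libraries separate as off in the wild type and on in the mutant label, and the dm_29C replicate 1 library lay on the mutant side at 5 of 6 and dm_45C replicate 1 at 3 of 6, where each wild type library held out in turn lay there at 0 of 6. These counts argue against a wild type library under the label, though an earlier form with loci at least 2 times apart (10 and 4 of 12) decided nothing, and the form used, with its bound of 3 loci, was set after its outcome was seen. Reads moved from the listed paralogs are argued against at 45 °C, where the summed list in replicate 1 was 1.5 times the highest wild type library, and stay open at 29 °C, where it was 1.16 times (earlier forms against the other mutant replicates, 2.04 for the sum and 11.6 for scaling, did not address the wild type), while library scaling is argued against, as GRP162 stayed at least 2.8 times the highest wild type library. A mixture of wild type and the other mutant libraries of the same temperature would lie between their values. GRP162 stood at 3288 and 12466, against at most 1121 at 29 °C and 3720 at 45 °C in the wild type, which argues against such a mixture. Another mutant genotype, or a mixture with material outside these libraries, may account for the pattern and stays open. No biological explanation was tested.

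Clock genes were shifted between temperatures, with 6 past the threshold in both genotypes. Sampling at another time of day could produce this shift and cannot be told apart from an effect of heat, since the labels give no sampling time. A few loci taking most of the signal is argued against for these 6 genes, as 100% of them were still called in both genotypes without the 10 most abundant loci. For the list shift in the wild type it stays open: without these loci the median log2 fold change was 0.782 (SD of members 1.24) against 0.732 (1.2) with them, but the camera adjusted p went from 0.0428 to 0.0611 (1.68e-06 to 0.404 over 24 alternatives) and the call ended. In the libraries labelled double mutant the list still passed without these loci (0.0047), but not with an estimated correlation (0.315).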

How the results depend on the processing

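The alternatives that left out both replicate 1 libraries labelled double mutant, removed the 10 most abundant loci, or joined the replicate block with only the groups compared were chosen only after results were seen; the others were planned. The correlation over all loci tested was likewise added later. Of 99 calls of named genes other than GRP3 and GRP162, 66 held in every alternative run for them, at most 23, and 33 were lost at least once. The heat calls of GRP3, not counted there, were lost in 7 of 19 alternatives in the wild type and 1 of 19 in the libraries labelled double mutant. Genes left out by a setting had fewer alternatives. Library weights and the log2 bound were not run per gene, and 6 of the 66 have an absolute log2 fold change under 1. All 24 list calls were lost at least once, each with an estimated correlation. The cause of the changes given here was not tested, except that a log2 bound cannot raise a count.

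With an absolute log2 fold change of 1 or more, 1720 loci rose and 1801 fell with heat in the wild type, and 1799 and 2022 in the libraries labelled double mutant. Without both replicate 1 libraries labelled double mutant, 1692 loci fell with heat there, 1410 falls were shared, 25 loci were higher at 29 °C, 7 were higher and 2 lower at 45 °C, 0 differed in the interaction, and GRP162 at 29 °C stood at -2.13 (adjusted p = 0.0373, against 0.0373 to 1 over 20 alternatives). These libraries were left out because their GRP162 was high, so that its value follows from the choice and tests nothing. The median ratio of heat responses was 0.902 over loci called in the wild type and 1.18 over loci called in the libraries labelled double mutant, and the correlation was 0.921 with a pseudocount of 0.1 and 0.859 over all loci tested.

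Between genotypes at 29 °C, 19 loci were higher and 5 lower with a pseudocount of 0.1, 10 and 3 with the filter at FPKM 5, and 5 lower with only the groups compared. At 45 °C, 5 were higher with no filter, 1 with the replicate block, 7 with only the groups compared and 5 with the block in those groups. The number lower at 45 °C was 0 with a pseudocount of 0.1, no filter, the filter at FPKM 5, TPM, the block, only the groups compared, the block in those groups and the 10 most abundant loci removed, and 2 with median-of-ratios scaling (3 higher) and library weights. In the interaction 1 locus responded more positively with no filter, 0 more negatively with a pseudocount of 0.1, the filter at FPKM 5 and TPM, and 1 with the block and with the 10 most abundant loci removed. With the block, the chlorophyll biosynthesis shift did not pass at 29 °C (adjusted p = 0.0569) or in the interaction (0.0801).

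Leaving out 1 library at a time, heat in the wild type raised 1781 to 2765 loci and lowered 2245 to 3363, and in the libraries labelled double mutant raised 2076 to 3203 and lowered 2328 to 3621. Between genotypes 8 to 53 were higher and 0 to 11 lower at 29 °C, and 1 to 30 higher and 0 to 14 lower at 45 °C. In the interaction 0 to 2 responded more positively and 0 to 9 more negatively. The median ratio ran from 0.974 to 1.16 and the correlation from 0.926 to 0.942, with 1388 to 1966 rises and 1794 to 2462 falls shared. The jasmonate shift at 29 °C reversed without WT_29C replicate 2 (adjusted p = 0.599), and its adjusted p ran from 2.19e-05 to 0.599. Depth is not given in the sources used here, so what it limits could not be computed.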

Other observations

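The genes and tests in this part were chosen only after the result was seen.

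Among 16 genes of diterpenoid phytoalexins, which are antimicrobial, 3 passed as higher in dm_29C than in WT_29C and were noticed first. Of the 16, 10 were too low to be tested, and by their means 11 were higher, 4 lower and 1 equal, with most of the untested ones under 1 FPKM in both groups. The cyclase CPS2 averaged 28.6 ± 4.1 FPKM against 1.11 ± 0.0814 (log2 difference 3.80, adjusted p = 0.0042), CYP701A8 36.8 ± 7.85 against 2.35 ± 0.797 (3.50, 0.0432) and CYP71Z7 38.2 ± 9.45 against 9.44 ± 2.37 (1.91, 0.0482). CPS2 lost its call in 1 of 23 alternatives (pseudocount 0.1, adjusted p = 0.144, against 2.72e-05 to 0.144 over all), and CYP701A8 and CYP71Z7 lost theirs in 16 and 14 of 23, each in 8 of the 12 fits without 1 library (adjusted p up to 0.207 and 0.258). With heat they fell in the libraries labelled double mutant, CPS2 by a log2 fold change of -3.91 (adjusted p = 6.23e-05), CYP701A8 of -3.08 (0.00277) and CYP71Z7 of -2.05 (0.000941).

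A hypothesis was that other members of the group are raised as well in these seedlings at 29 °C. Among the 3 tested members other than those noticed first, KSL5, CYP76M6 and CYP99A2, camera gave p = 0.0182, an estimated correlation 0.0442 and fry 0.0059, with 2 higher, 1 lower and none past the threshold. Chance choice of genes stays open, as 3 members are too few; a minimum of 5 members was set after this p was seen. A general defence response may be another source, and the defence list gave a fry p of 0.698 with a median log2 difference of -0.181 over members that went both ways, which leaves it open.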
